A study of Homo sapiens with 6 samples.

How the data were processed

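RNA was profiled in 6 libraries of sorted human CD4+ effector T cells, 3 treated with CITCO and 3 with DMSO for 24 h. Per the labels' protocols, cells were kept with interleukin-2 at 10 U/mL, total RNA had an integrity number above 9, 400 ng entered ribosomal RNA depletion and a strand-specific library kit with 10 PCR cycles, and sequencing gave 40 bp paired ends. Whether unspliced or non-polyadenylated RNA contributes to the counts was not tested; histone genes held 0.0334% to 0.0407% of the counts of a library. PCR duplicates cannot be recognised in a table of counts.

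The deposited table holds estimated counts per gene, which the authors made with Salmon against GRCh38, per the submitters' processing notes. These notes also name DESeq2. Versions, the transcript annotation and filters are not given in the sources used here. Per the file headers, transcript estimates were summed to 35183 genes without scaling counts by abundance, and libraries were kept in separate columns. Estimated counts divide reads that fit several transcripts, so genes with near-identical or overlapping copies are uncertain. All 35183 gene identifiers were found in GENCODE release 29, which supplied GRCh38 coordinates, and 34994 had a current symbol in the name table. The 6 count columns were used. The other 12 value columns of the table, with abundances and lengths, were not used here. The count columns name the group and carry no replicate number, so libraries are named a, b and c after their column suffix.

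Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR (at least 10 counts in enough libraries for the smallest group and 15 in all), which left 13897 genes holding at least 99.79% of the counts of each library. Libraries were scaled by TMM, and CPM is the count per 1e6 of the scaled library total. The planned test was the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), CITCO against DMSO with no covariate and Benjamini-Hochberg adjustment over all genes at 0.05. SE was taken as the size of the log2 fold change divided by the square root of the F statistic, and 95% intervals from it with the test's degrees of freedom. For a very large change from few counts, as for CYP2B6, this SE can lie below the counting error. Principal components and within-set differences used log2 CPM with a prior count of 2.

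Because the values fell into 3 sets, the same test was repeated with the set as an added factor, with DESeq2 1.42.0 and limma-voom as alternatives. This fit was chosen after the data were seen, and sets were taken from column suffixes and from the closest library, with 6 possible matchings of 3 CITCO with 3 DMSO libraries. It could not be tied to the replicate numbers in the labels, and took the place of a fit by those numbers in the rule for naming genes. The planned naming condition that the groups do not overlap was read, in the set fit, as the same sign in 3 of 3 sets.

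Gene lists, fixed genes, the main test and its first alternatives were set before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 of 48 lists with at least 5 measured members. The other 7 are given by counts only. An estimated correlation and fry were alternatives. Genes are named by a rule: the fixed genes, then per direction up to 10 genes with the largest change past the threshold whose groups do not overlap and whose mean is at least 1 CPM. Places left are filled from the fit with the set as an added factor, then by the smallest p. Per list, 2 to 4 members with the smallest p are named. Clone-named and non-coding genes, pseudogenes, and 121 genes that are T cell receptor, immunoglobulin or HLA genes or whose level can reveal sex were left out of naming or of per-gene output. A few genes that met the rule are not reported here.

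Depth was 26724907 to 37223762 counts per library, so that 3 counts, the limit that a count of 0 allows at 95% confidence, correspond to 0.082 to 0.107 CPM. Intervals and limits cover counting error or the spread of these libraries only. Scripts were tested on 1 set of simulated counts, drawn from the mean of each gene in each set, its dispersion within sets and the library sizes, with 200 genes changed before the filter. At log2 fold changes of 0.5, 1 and 2, edgeR without an added factor recovered 0%, 28.4% and 66.7% of changed genes among 13658 with 0 false calls. With the set as an added factor it recovered 63.1%, 76.1% and 95% with 29 false calls, which is above the nominal share. Alternatives covered scaling, filter, test, threshold, fold minimum, leaving out each library or set, and the list test.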

Results

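The series measured gene expression in human CD4+ effector T cells that carried integrin α4β7 and the chemokine receptor CCR9, a pair of receptors that direct lymphocytes to the gut. The cells were sorted from blood mononuclear cells, activated with beads against CD3 and CD28 in the presence of interleukin-2, and exposed for 24 h to CITCO or to its solvent DMSO. CITCO is a small-molecule agonist of the human constitutive androstane receptor (CAR, encoded by NR1I3), a nuclear receptor known mainly from liver, where it induces enzymes and transporters for drugs and bile acids. The series title, the sample titles, the treatment protocol and the count columns name CITCO, at 10 µM where a dose is given, whereas the treatment tag of the treated samples and the design text name 50 µM of a compound abbreviated TC. The treated group is called CITCO throughout, and its dose is left open between these entries. Each group held 3 libraries. Estimated counts summed to between 26724907 and 37223762 per library, the most abundant gene was EEF1A1 at 1.95% to 2.43% of all counts, and 13897 genes were tested. Nothing in the labels says whether the 3 libraries of a group came from separate donors or cultures, so p-values measure the spread between these libraries, which may be technical in part.

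The libraries fell into 3 matched sets of 1 CITCO and 1 DMSO library each. In 6 of 6 libraries the closest library by Spearman correlation of log2 CPM belonged to the other treatment and had the same column suffix in the deposited table. Across the 13897 genes, deviations from the group means correlated at 0.62 to 0.66 between libraries of a set and at -0.37 to -0.22 between CITCO and DMSO libraries of different sets. The deviations of a group sum to 0 for each gene, so positive values within sets require negative ones between sets. The first and second principal components, with 41% and 32.9% of the variance, separated the sets, and the third, with 10.1%, separated CITCO from DMSO. The common biological coefficient of variation was 25.3% when libraries were treated as unmatched and 6.07% with the set as an added factor. The planned comparison left the sets out. Values within sets, from the fit with the set as an added factor, are therefore printed beside it. The sets were recognised in the values and in the order of column suffixes, not in the sample labels.

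**Figure D1:**
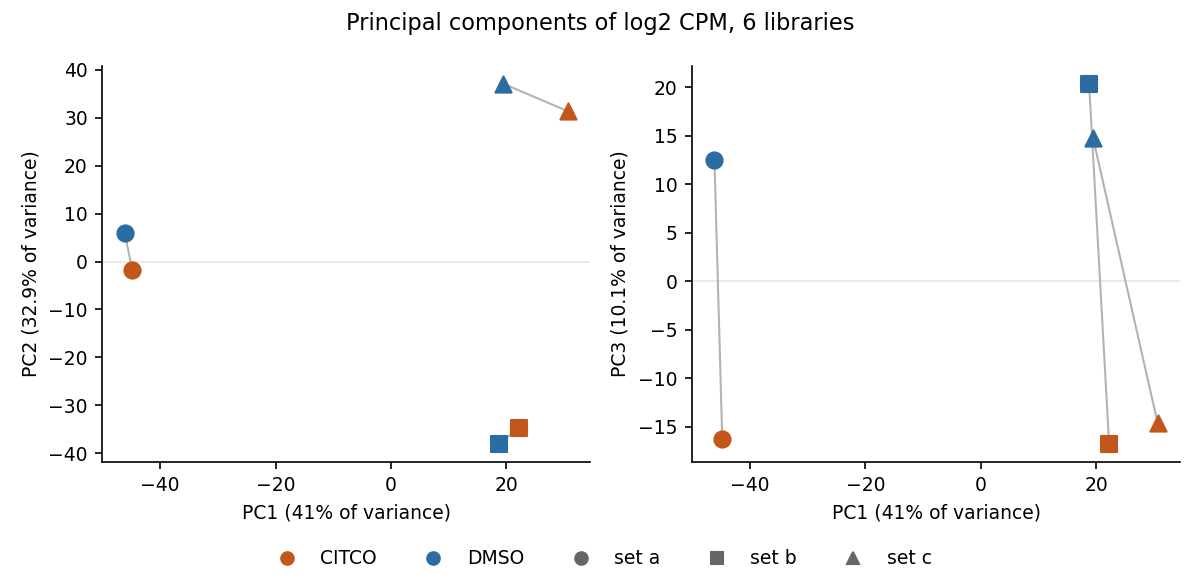
Principal components of log2 CPM for the 6 libraries, coloured by treatment, with the marker shape giving the set and a grey line joining the libraries of a set. The first component (41% of variance, horizontal in both panels) and the second (32.9%, left panel) separate the sets, and on the third (10.1%, right panel) the 3 CITCO libraries lie below 0 and the 3 DMSO libraries above 0.

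CYP2B6, a drug-metabolising cytochrome P450 that is the textbook target of CAR in human liver, rose from close to the detection limit to a moderately expressed gene. Its level was 57.4 ± 14.8 CPM with CITCO and 0.230 ± 0.094 CPM with DMSO (SD, n = 3 each), a 245-fold difference with a 95% interval of 141 to 425 (log2 fold change 7.94 ± 0.34, SE; edgeR adjusted p = 0.00077). The gene (ENSG00000197408) lies on chromosome 19 from 40991250 to 41018398 in GRCh38. The difference rested on 5635 counts in the CITCO libraries against 21 in the DMSO libraries, and the lowest CITCO library, at 44.5 CPM, lay 140-fold above the highest DMSO library, at 0.318 CPM. Within sets the log2 fold change was 7.94 (adjusted p = 1.76e-08). The SE taken from the F statistic, 0.14 within sets, is too small for a change this large that rests on 21 DMSO counts. Differences of log2 CPM were 8.13, 7.59 and 7.19 in sets a, b and c, and leaving out each set gave fitted values of 7.7 to 8.12. DESeq2 gave 7.96 ± 0.39 (SE) in the planned comparison. CYP2B7P, a pseudogene of near-identical sequence whose reads a quantifier could share with CYP2B6, had 8 counts in the CITCO and 13 in the DMSO libraries.

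CYP2B6 was the only gene past the threshold in the planned comparison, with 1 gene higher and 0 lower. At an unadjusted p under 0.05 there were 97 genes, 53 higher and 44 lower, against 695 that chance would give with evenly spread p-values. The error of this comparison includes the spread between sets, so the low count does not show that other genes were unchanged. DESeq2 called 4 genes higher and 2 lower, and limma-voom called 2 higher and 2 lower. Besides CYP2B6 the DESeq2 calls included GJB2, which encodes a gap junction protein (log2 fold change -1.14 ± 0.24, adjusted p = 0.00753). GJB2 and the gene pairs with overlapping or near-identical sequence described after this report were chosen after their values were seen. With the set as an added factor, edgeR called 4 genes higher and 11 lower, and 1377 genes had an unadjusted p under 0.05 (594 higher, 783 lower), against the same 695. In simulated counts this fit made 29 false calls among 13658 tested genes. These stood beside 41, 51 and 57 changed genes that it recovered at log2 fold changes of 0.5, 1 and 2. That share of false calls is more than the threshold allows, so some of the calls in the real data are expected to be false. How many cannot be read from the 29, because the simulated counts held their own fixed number of changed genes.

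By fold change, and with clone-named genes left out, the largest falls within sets that passed were in cytokines of type 17 and related T cells. IL17F, which encodes an interleukin that drives neutrophil recruitment at mucosal surfaces, fell to 47.0% of its DMSO level within sets (log2 fold change -1.09 ± 0.07, adjusted p = 0.000425). IL22, whose product acts on epithelial cells, fell to 51.2% (-0.97 ± 0.11, adjusted p = 0.016), and IL24, a cytokine of the IL-10 family, to 48.9% (-1.03 ± 0.12, adjusted p = 0.0222). Levels differed widely between sets. IL17F ranged from 21.4 to 97.9 CPM in the DMSO libraries and from 9.00 to 49.4 CPM in the CITCO libraries, so that its planned comparison gave -1.04 ± 0.80 with an adjusted p of 1.00. When each library was left out of it, the log2 fold change ranged from -2.17 (without CITCO library c) to -0.03 (without DMSO library c) for IL17F, from -1.57 to -0.42 for IL22 and from -1.40 to -0.67 for IL24. Leaving out 1 library unbalances the sets, so these ranges also hold the difference between sets. Within sets, leaving out each set gave -1.17 to -1.02 for IL17F, -1.18 to -0.85 for IL22 and -1.13 to -0.85 for IL24. The values of IL22 were 24.3 ± 18.5 CPM with CITCO and 45.1 ± 28.6 with DMSO, and those of IL24 were 6.56 ± 2.42 and 13.8 ± 6.81 (SD, n = 3 each). These genes lie in GRCh38 at 52236681 to 52244537 on chromosome 6 (IL17F), 68248242 to 68253604 on chromosome 12 (IL22) and 206897443 to 206904139 on chromosome 1 (IL24).

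The other named falls within sets concerned genes of varied function. MYOF, which encodes the membrane-repair protein myoferlin, fell to 62.9% (log2 fold change -0.67 ± 0.04, adjusted p = 0.000425), and LMNA, which encodes the nuclear lamins A and C, to 70.4% (-0.51 ± 0.04, adjusted p = 0.00121). SYTL3, a synaptotagmin-like gene of vesicle traffic, reached -0.50 ± 0.05 (adjusted p = 0.00657), ASB2, part of a ubiquitin ligase, -0.49 ± 0.06 (adjusted p = 0.0281), and MYO1G, a myosin of blood cells, -0.36 ± 0.05 (adjusted p = 0.0335). CABLES1, a regulator of cyclin-dependent kinases, reached -0.91 ± 0.12 (adjusted p = 0.0369) and DDIT4, an inhibitor of the growth kinase mTORC1, -0.31 ± 0.04 (adjusted p = 0.0471). The rises within sets besides CYP2B6 included LBH, a transcription cofactor (0.44 ± 0.05, adjusted p = 0.0261), and APOL6, an apolipoprotein L gene (0.36 ± 0.04, adjusted p = 0.0222). None of these genes passed in the planned edgeR comparison, where each had an adjusted p of 1.00 and log2 fold changes were -0.66 ± 0.19 for MYOF, -0.51 ± 0.28 for LMNA, 0.45 ± 0.19 for LBH and 0.36 ± 0.26 for APOL6. When each library was left out of it, these ranged from -0.81 to -0.51, -0.75 to -0.27, 0.32 to 0.61 and 0.14 to 0.59 in the same order. Within sets, leaving out each set gave -0.69 to -0.65, -0.51 to -0.49, 0.36 to 0.49 and 0.354 to 0.385 in this order. Without set b, 9 of the 15 calls were lost, including those of LBH (adjusted p = 0.101), APOL6 (0.15), IL22 (0.109), IL24 and MYO1G (0.0632 each), CABLES1 (0.136), ASB2 (0.192) and DDIT4 (0.115). Without set a, CABLES1 (0.108) and DDIT4 (0.0889) were lost. DDIT4 was also lost with the size factors of DESeq2 (0.0501) and with a stricter filter (0.0564), and passed in 4 of 8 alternatives.

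**Figure D2:**
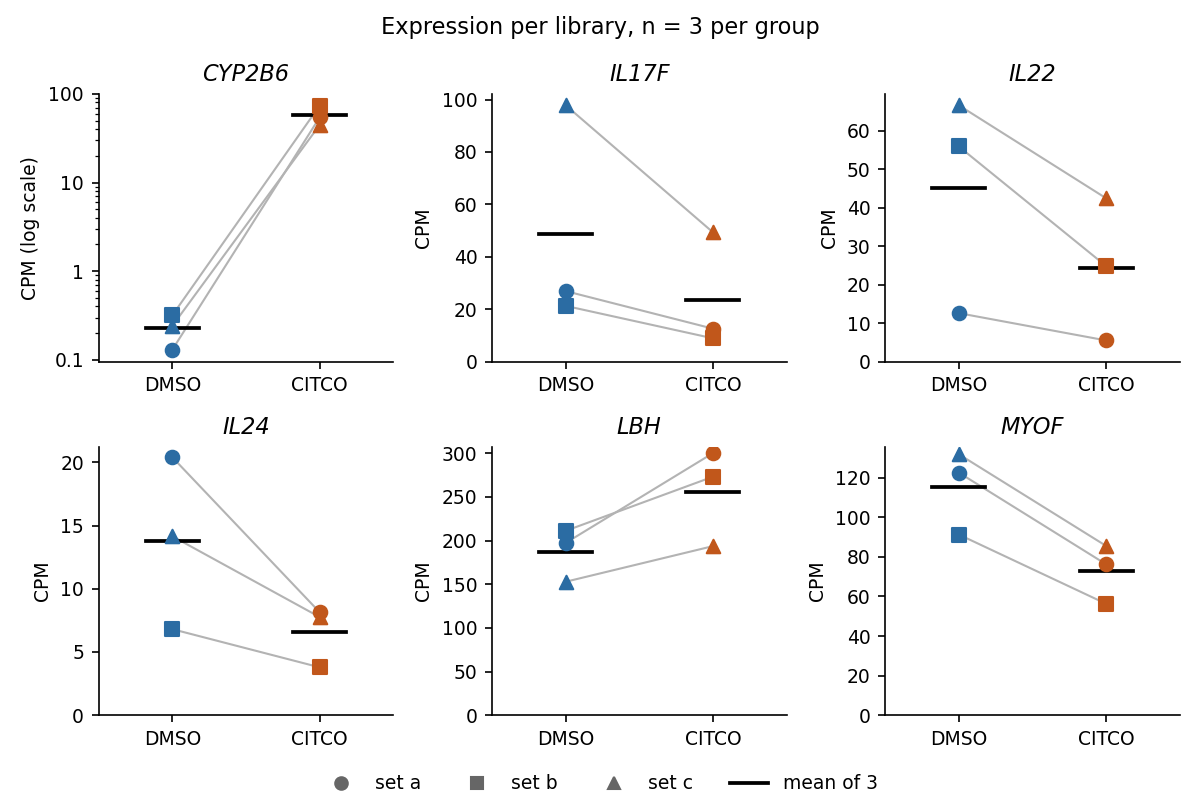
CPM per library of 6 genes, for the DMSO (blue) and CITCO (orange) libraries, with the marker shape giving the set, grey lines joining the libraries of a set and black bars the mean of 3 libraries. CYP2B6 has a log axis and lies between 44.5 and 73.5 CPM with CITCO against 0.130 to 0.318 with DMSO, and the other panels have linear axes from 0, where in each set IL17F, IL22, IL24 and MYOF are lower and LBH is higher with CITCO.

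The places left by the naming rule for rises went to genes that did not pass in edgeR. These included ZBED6 (log2 difference within sets 0.74 ± 0.11), GBP5 (0.29 ± 0.04), the co-stimulatory receptor gene CD28 (0.28 ± 0.04), PELI1 (0.27 ± 0.04) and DOCK10 (0.25 ± 0.04), with adjusted p from 0.0651 to 0.088. All 5 were higher with CITCO in 3 of 3 sets. With the set as an added factor DESeq2 called all 5, with adjusted p of 0.000296 for ZBED6, 9.67e-07 for GBP5, 1.98e-05 for CD28, 0.0207 for PELI1 and 0.000171 for DOCK10. Limma-voom called 4 of them (0.0312 for GBP5, 0.037 for DOCK10 and CD28, 0.0462 for ZBED6) and not PELI1 (0.0672).

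Genes fixed in advance as markers of the receptor, the drug response and the cell type did not pass the threshold in either edgeR fit apart from CYP2B6. NR1I3 itself was near the detection limit, with 3 to 12 counts per library (0.219 ± 0.117 CPM with CITCO and 0.351 ± 0.051 with DMSO, SD, n = 3 each), where 3 counts correspond to 0.082 to 0.107 CPM. It was lower in 3 of 3 sets, with a log2 difference of -0.72 and a wide 95% interval of -1.92 to 0.48 (adjusted p = 0.713). Set b, where the CITCO library had 3 counts, carried most of this (-1.52, against -0.20 and -0.21 in the others), and the planned value of -0.68 became -0.31 without CITCO library b. CYP3A4, a drug-metabolising enzyme shared as a target by CAR and the pregnane X receptor, had 7 counts in the CITCO and 3 in the DMSO libraries and was not tested. ABCB1, the drug and bile acid exporter also called MDR1, was at 14.0 ± 1.09 CPM with CITCO and 12.2 ± 1.55 with DMSO, a log2 difference within sets of 0.20 with a 95% interval of -0.04 to 0.43 (adjusted p = 0.588). IL10 was at 69.5 ± 34.9 against 88.8 ± 48.8 CPM (within sets -0.30, interval -0.77 to 0.17, adjusted p = 0.688). The planned comparison gave ABCB1 0.20 ± 0.15 and IL10 -0.35 ± 0.51. The sign of IL10 turned when a library was left out of it, with a range of -0.81 to 0.09.

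IFNG, the type 1 cytokine interferon-γ, was lower with CITCO in 3 of 3 sets without passing the threshold in edgeR (log2 difference -0.27 ± 0.05, adjusted p = 0.0938; 905 ± 517 CPM with CITCO and 1062 ± 522 with DMSO). IL17A was also lower in 3 of 3 sets (-0.36 ± 0.10, adjusted p = 0.286), as was the integrin β7 gene ITGB7 (-0.27 ± 0.04, adjusted p = 0.088). Within sets DESeq2 called IFNG (adjusted p = 1.83e-05) and ITGB7 (0.0125) lower, and limma-voom called neither (0.0681 each). The integrin α4 gene ITGA4 differed by 0.01 ± 0.04 (149 ± 19.2 CPM with CITCO, 148 ± 11.2 with DMSO), with an interval of -0.09 to 0.10. The planned comparison gave -0.23 ± 0.51 for IFNG, -0.38 ± 0.20 for IL17A, -0.25 ± 0.54 for ITGB7, 0.01 ± 0.11 for ITGA4 and 0.21 ± 0.33 for CCR9. Leaving out single libraries, which unbalances the sets, turned the sign for IFNG (-0.74 to 0.17), ITGB7 (-0.75 to 0.20), ITGA4 (-0.10 to 0.07) and CCR9 (-0.10 to 0.37). CCR9, one of the receptors used for the sort, was at 1.47 ± 0.49 and 1.27 ± 0.24 CPM (0.18 ± 0.26, interval -0.42 to 0.78).

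**Figure D3:**
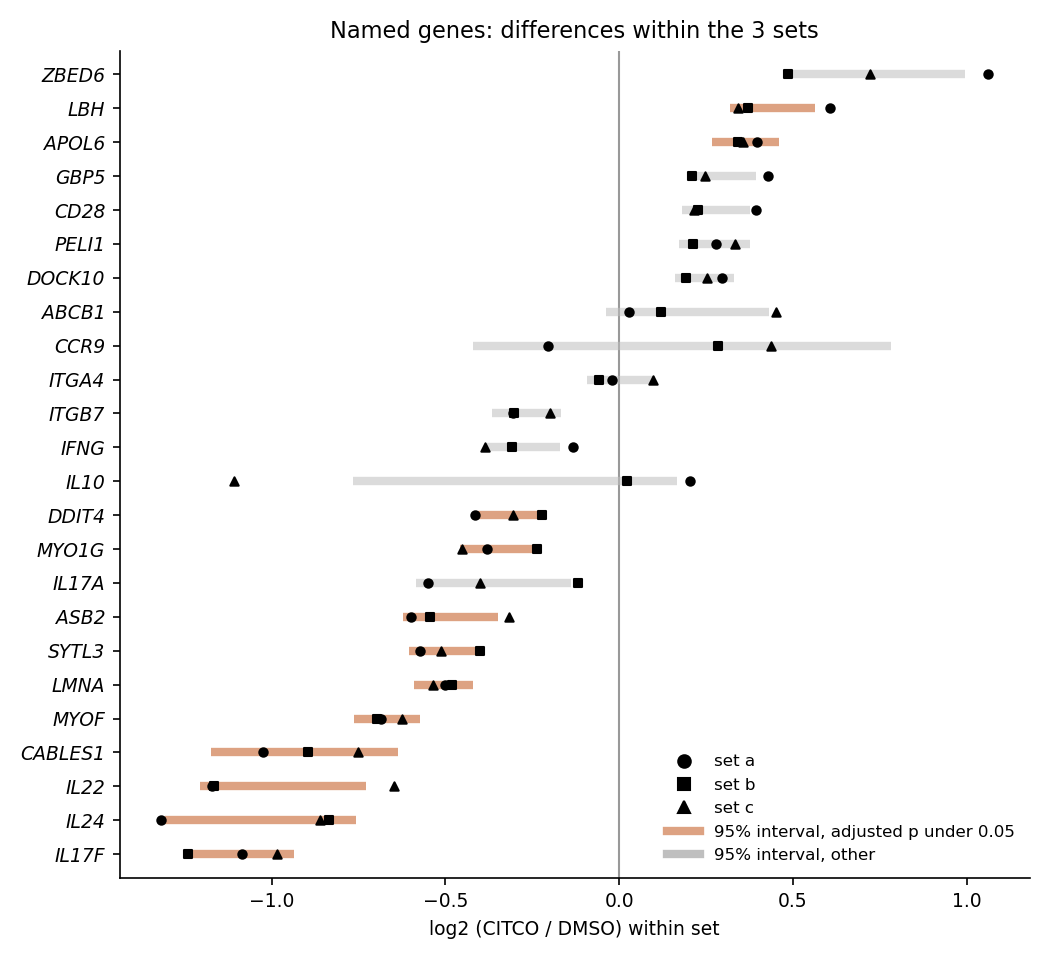
Differences between CITCO and DMSO on a log2 scale within each set (markers) for 24 named genes, with bars for the 95% interval of the edgeR fit with the set as an added factor, orange where the adjusted p is under 0.05. The orange bars run from IL17F at -1.09 to LBH at 0.44, and the bars of ABCB1, CCR9, ITGA4 and IL10 include 0.

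Of the 41 gene lists with at least 5 measured members, camera placed 3 higher and 8 lower than the other genes in the planned comparison. It placed 7 higher and 12 lower with the set as an added factor, and 10 lists were called in the same direction by both. None was called with an estimated correlation, where the smallest adjusted p was 0.2 in the planned comparison and 0.5 within sets, or by fry, which tests a list on its own (0.78 and 0.114). With an estimated correlation the test has few degrees of freedom in so few libraries. Its lack of calls therefore cannot tell correlation between genes from low power. The list of CAR and pregnane X receptor targets had an estimated correlation of -0.0381 within sets and still an adjusted p of 0.5. Among the lists called within sets, the estimate ranged from -0.0652 (liver X receptor targets) to 0.814 (DNA synthesis), against the preset 0.01. Where the estimate lies far above the preset, members vary together and the preset camera p is too small. Regroupings of the libraries also gave list calls, as stated in the closing section. The lists are therefore described by their members, with the camera p as a description.

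CAR and pregnane X receptor targets were called higher by camera (adjusted p = 1.81e-11, and 1.27e-14 within sets; adjusted p = 0.2 and 0.5 with an estimated correlation), on the strength of CYP2B6. Of 18 measured members 1 rose and 0 fell, both over all genes and adjusted over the list alone. Without CYP2B6 the other 17 had a median log2 difference within sets of -0.02, 7 positive and 10 negative, and camera gave an adjusted p of 0.551 in the planned comparison and 0.626 within sets. GADD45B, a growth-arrest gene, differed by 0.14 ± 0.07 and INSIG1, a regulator of sterol synthesis, by -0.08 ± 0.04. The mean of all 18 was 0.48 and their median -0.01, so that mean and median differed in sign.

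Cytokine genes were called lower (camera adjusted p = 0.000231, and 2.08e-12 within sets; adjusted p = 0.733 and 0.5 with an estimated correlation). Of 44 measured members 0 rose and 3 fell within sets over all genes, and 10 fell when adjusted over the list alone. The members had a median log2 difference of -0.13, and 35 of 44 were negative. The planned call was lost without CITCO library b (adjusted p = 0.31), DMSO library a (0.0584) or DMSO library c (0.136), and the call within sets held without each set. The type 17 list, which shares IL17F and IL22 with the cytokines, had a median of -0.03 over 18 members and was called lower only within sets (adjusted p = 0.00453; adjusted p = 0.5 with an estimated correlation). Its members went both ways: 4 were higher and 4 lower when adjusted over the list alone, among them IL26, a further cytokine of these cells, at -1.14 ± 0.26 and the transcription factor gene IRF4 at 0.12 ± 0.03, neither of which passed over all genes.

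Targets of the aryl hydrocarbon receptor (AHR), a sensor of dietary and xenobiotic ligands, were called lower in the planned comparison (camera adjusted p = 0.00494) but not within sets (0.0687). The adjusted p was 0.733 and 0.772 with an estimated correlation. The planned call was lost without CITCO library a (0.466) or DMSO library b (0.289). Of 9 measured members 0 passed over all genes, and 1 was higher and 4 lower when adjusted over the list alone within sets. The 4, of which CYP1A1 is named beyond the rule for list members, were CYP1A1 (log2 difference -1.25 ± 0.38, at 0.611 ± 0.249 CPM with CITCO and 1.41 ± 0.24 with DMSO), CYP1B1 (-1.21 ± 0.29), AHRR (-0.61 ± 0.14) and TIPARP (-0.39 ± 0.12). Other induced genes of this receptor differed from 0 by less than their SE, with CYP1A2 at 0.23 ± 0.31 and NQO1 at 0.10 ± 0.21. Neither passed either adjustment, and AHR itself was at 0.16 ± 0.04. The list's median was 0.02 and its mean -0.31, which differ in sign.

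Cell-cycle lists were called lower. All 28 measured genes of the transition to DNA synthesis had a negative log2 difference within sets, with a median of -0.24 (camera adjusted p = 1.83e-06, and 8.69e-11 within sets; adjusted p = 0.733 and 0.61 with an estimated correlation). The estimated correlation between these genes was 0.7 in the planned comparison and 0.814 within sets, so the 28 shared signs are not independent. None passed over all genes and 2 fell when adjusted over the list alone, MCM2 (-0.29 ± 0.07) and MCM5 (-0.25 ± 0.06), subunits of the replicative helicase. Mitosis genes had a median of -0.15 with 21 of 26 negative (camera adjusted p = 0.0191, and 0.0249 within sets, and 0.733 and 0.772 with an estimated correlation). Without set c the mitosis list lost its call within sets (adjusted p = 0.991) and its direction turned. KIF23, a kinesin of cytokinesis, differed by -0.75 ± 0.18 and the cyclin gene CCNB1 by -0.24 ± 0.10, neither past the threshold. The planned calls of both lists were lost without CITCO library b (0.0516 for DNA synthesis, 0.813 for mitosis), CITCO library c (0.192 for both) or DMSO library a (0.325 and 0.547), and that of mitosis also without DMSO library c (0.839).

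Lists of respiration and ribosome assembly moved by small amounts, and the metallothionein list by more. The 13 protein genes of the mitochondrial genome had a median of -0.09, 12 of 13 negative, and 9 fell when adjusted over the list alone (camera adjusted p = 0.0346, and 2.39e-06 within sets; adjusted p = 0.733 and 0.5 with an estimated correlation). MT-ND4, a subunit of complex I, was at 3895 ± 716 CPM with CITCO and 4319 ± 852 with DMSO (-0.15 ± 0.02 within sets, adjusted p = 0.081). Nuclear genes of oxidative phosphorylation had a median of -0.05 with 27 of 30 negative and 0 past either adjustment, with the complex I gene NDUFV1 at -0.15 ± 0.04 and the complex IV gene COX8A at -0.16 ± 0.07. Genes of ribosome assembly and MYC had a median of -0.05 with 24 of 25 negative and 0 past either adjustment, with the ribosome assembly gene PPAN at -0.16 ± 0.04 and the spermidine synthase gene SRM at -0.17 ± 0.04. Both lists had a camera adjusted p of 0.0346 (0.733 with an estimated correlation), and 0.00257 and 0.000214 within sets (0.61 and 0.5 with an estimated correlation). Without set b the ribosome assembly list lost its call within sets (0.106). Ribosomal protein genes, at a median of -0.01 over 32 members, were not called (adjusted p = 0.88, and 0.769 within sets). The 6 measured metallothionein-list genes, which bind zinc and other metals or export zinc, were all negative with a median of -0.31 (camera adjusted p = 0.00525, and 4.53e-05 within sets; adjusted p = 0.535 and 0.5 with an estimated correlation), with MT2A at -0.49 ± 0.09 and MT1X at -0.27 ± 0.07 falling when adjusted over the list alone. The planned calls were lost for the mitochondrial genome without CITCO library a (0.92), CITCO library c (0.172) or DMSO library b (0.908), for oxidative phosphorylation without CITCO library b (0.16), CITCO library c (0.631) or DMSO library a (0.74), for ribosome assembly without CITCO library c (0.96), DMSO library a (0.515) or DMSO library b (0.713), and for the metallothionein list without CITCO library b (0.16), DMSO library a (0.0584) or DMSO library c (0.173). The direction of the mitochondrial genome and ribosome assembly lists also turned when a library was left out.

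Interferon-response genes were called higher (camera adjusted p = 0.00181, and 2.18e-07 within sets; adjusted p = 0.733 and 0.643 with an estimated correlation). They had a median log2 difference within sets of 0.12 over 36 members, 33 of them positive. Their estimated correlation was 0.56 in the planned comparison and 0.652 within sets, so these signs are not independent. None passed over all genes and 5 rose when adjusted over the list alone, including the guanylate-binding protein genes GBP5 (0.29 ± 0.04), GBP1 (0.21 ± 0.04) and GBP2 (0.16 ± 0.03) and the transcription factor gene IRF1 (0.17 ± 0.04). The planned call was lost without CITCO library b (0.529) or DMSO library a (0.35), and the direction of the list turned when a library was left out. Genes of naive and memory T cells were called higher only within sets (adjusted p = 0.000893; adjusted p = 0.5 with an estimated correlation), with a median of 0.08 over 17 members. Of these, 5 rose and 1 fell when adjusted over the list alone. CD28, the lymph-node homing receptor gene CCR7 (0.26 ± 0.04) and the cytokine receptor gene IL7R (0.23 ± 0.05) were among those that rose, and S1PR1, a receptor for exit from lymph nodes, fell (-0.26 ± 0.05).

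Stress-related lists were also called higher. The list of the integrated stress response had a median of 0.08 over 29 members, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0481, and 0.00151 within sets; adjusted p = 0.733 and 0.5 with an estimated correlation). The enzymes of serine and asparagine synthesis PSAT1 (0.28 ± 0.06) and ASNS (0.14 ± 0.04) were among those that rose, and DDIT4 fell. The planned call was lost without CITCO library a (0.0547), CITCO library b (0.704), DMSO library a (0.325) or DMSO library c (0.887), and the direction of the list turned when a library was left out. Oxidative-stress and lysosome genes were called higher only within sets (adjusted p = 0.0187 and 0.0206; 0.772 and 0.552 with an estimated correlation), and share SQSTM1, an autophagy receptor gene, at 0.27 ± 0.05. The list of cell-death regulators was called higher within sets (0.0249; 0.509 with an estimated correlation), with BCL2L11, which promotes apoptosis, at 0.18 ± 0.04 and BCL2, which opposes it, at 0.16 ± 0.04. Of its 26 members 3 were higher and 1 lower when adjusted over the list alone, the 1 being BIRC3, an inhibitor of apoptosis, at -0.12 ± 0.03. Calls within sets were lost for oxidative stress (0.793) and lysosome (0.163) without set c, and for cell death without set a (0.194). The direction of the oxidative-stress list also turned without set c.

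Of the lists related to lipids, targets of the liver X receptors were called lower within sets (median -0.18 over 9 members, adjusted p = 0.0199; 0.5 with an estimated correlation), as were genes of fatty acid synthesis (median -0.15 over 11 members, adjusted p = 0.0249; 0.509 with an estimated correlation). These lists share SCD and SREBF1, so their calls are not independent. No member of either list passed over all genes or over the list alone. ABCG1, a cholesterol exporter gene, was at -0.40 ± 0.13 and FASN, the fatty acid synthase gene, at -0.16 ± 0.05. Glycolysis genes (median -0.05 over 28 members, adjusted p = 0.0425; 0.5 with an estimated correlation) and regulatory T cell genes (median -0.08 over 14 members, adjusted p = 0.0479; 0.61 with an estimated correlation) were called lower within sets as well. Adjusted over the list alone, 0 glycolysis genes were higher and 3 lower, among them PFKFB3, an activator of glycolysis, at -0.18 ± 0.04. Of the regulatory T cell genes 1 was higher and 3 lower by that adjustment: the transcription factor gene IKZF2 was higher (0.29 ± 0.09), and the receptor genes TIGIT (-0.19 ± 0.05) and TNFRSF18 (-0.27 ± 0.07) were among the lower. Calls were lost for liver X receptor targets without set c (0.144), for glycolysis without set a (0.087) or b (0.383), and for regulatory T cell genes without set a (0.194) or c (0.144).

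The lists of drug transporters, nuclear receptors and homing were not called by camera in either fit. Drug transporters had a median of -0.05 over 23 members (adjusted p = 0.417, and 0.28 within sets), with the lipid transporter gene ABCA2 at -0.30 ± 0.08 and ABCG1 at the value given above. Nuclear receptors had -0.04 over 26 (0.88 and 0.959), with the retinoic acid receptor gene RARG at -0.21 ± 0.06 and the activation-induced NR4A2 at -0.37 ± 0.11, and the homing and migration list 0.00 over 24 (0.669 and 0.376). In the homing list 4 genes rose and 6 fell within sets when adjusted over the list alone, including CCR7 (0.26 ± 0.04) and ITGB7 (-0.27 ± 0.04). Retinoic acid genes (median -0.02 over 12 members) and type 1 genes (0.03 over 18) were also not called, with adjusted p of 0.335 and 0.672 within sets, and 0 and 2 members higher and 2 and 3 lower when adjusted over the list alone. The activation list had a median of -0.01 over 32 members (adjusted p = 0.957, and 0.657 within sets), with 3 higher and 6 lower when adjusted over the list alone.

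Most markers of other blood cells were scarce in both groups. CD8A had 22 counts in the CITCO and 30 in the DMSO libraries, the B cell gene MS4A1 had 3 and 1, the monocyte gene LYZ had 23 and 26, the natural killer cell gene NCAM1 had 2 and 3, and the platelet genes PF4 and PPBP had 0 in both. Exceptions included CD79B at 11.1 ± 3.06 CPM with CITCO and 12.2 ± 2.72 with DMSO, and CD68 at 6.43 ± 1.00 and 6.42 ± 1.5, genes of B cells and macrophages that other cells can express. For comparison, the CD4 T cell identity list (14 measured members) had a median log2 difference of -0.05 within sets (camera adjusted p = 0.28).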

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

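Fits within sets and their alternatives were chosen after the data were seen. No paired analysis was possible by the labels' replicate numbers, because the count columns carry no replicate number; the fits within sets rest on column suffixes instead. CYP2B6 passed in every alternative run, with a log2 fold change of 7.65 to 8.25 when each library was left out, and was the 1 gene higher with CITCO under another scaling, under both filters and without any 1 library. Of the genes lower with CITCO, none in edgeR became 1 without a filter or at an adjusted p under 0.1. DESeq2 gave 4 higher and 2 lower, limma-voom 2 and 2. With the set as an added factor the counts were 4 higher and 11 lower with edgeR, 28 and 53 with DESeq2, and 12 and 21 with limma-voom, and DESeq2 and limma-voom each included the 15 of edgeR. Within sets, no filter gave 160 higher and 195 lower over 22599 genes, an adjusted p under 0.01 gave 1 and 5, under 0.1 gave 16 and 24, and an absolute log2 fold change of at least 1 gave 1 and 3. Leaving out a set gave 3 to 47 higher and 7 to 61 lower, the most without set c and the fewest without set b. Of the 15 genes, 6 passed in all 8 other settings at the same threshold: CYP2B6, IL17F, MYOF, LMNA, SYTL3 and the clone-named AC008758.1. The cause of the other differences was not tested. Leaving out libraries also lowers the number of samples, and leaving out a single library unbalances the sets.

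Of gene lists, 3 higher and 8 lower became 7 higher and 12 lower with the set as an added factor, and 0 and 0 with an estimated correlation or fry, in both fits. Leaving out each library gave 1 to 6 higher and 2 to 7 lower. Lists whose direction turned when a library was left out, with the range of adjusted p over the 6 left-out libraries, were the integrated stress response (1.47e-05 to 0.887), interferon response (4.46e-06 to 0.529), genes of the mitochondrial genome (1.13e-05 to 0.92) and genes of ribosome assembly and MYC (3.08e-05 to 0.96). Within sets, the oxidative-stress list (5.67e-05 to 0.793) and the mitosis list (0.00153 to 0.991) turned, both without set c, which ended their calls. Genes whose sign turned when a library was left out, none of them past the threshold in edgeR, had log2 fold changes of -0.81 to 0.0857 (IL10), -0.74 to 0.17 (IFNG), -0.10 to 0.37 (CCR9), -0.10 to 0.0719 (ITGA4) and -0.75 to 0.20 (ITGB7). Within sets the sign turned without set c for IL10 (-0.58 to 0.12) and ITGA4 (-0.0428 to 0.0454). DESeq2 with the set as an added factor called IFNG (adjusted p = 1.83e-05) and ITGB7 (0.0125). Depth limits NR1I3 and CYP3A4, whose counts lie near the floor, and the spread between sets limits the planned comparison, which recovered 0% of simulated changes of 0.5.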

Other observations

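The tests on CYP2B6 and on the cytokines, the gene pairs, and all fits with the set as an added factor were chosen only after the results were seen, and the depth and receptor-segment tests after the sets were recognised but before their own values were computed. In 1 pair of overlapping genes counts moved between the genes with treatment while their sum changed little. AC008758.1, a clone-named gene on chromosome 19 from 12461559 to 12551474, had 69 to 84 counts in the DMSO libraries and 0 in the CITCO libraries. ZNF709, a zinc-finger gene that overlaps it on the same strand from 12461184 to 12513854, had 25 to 65 counts in the DMSO and 118 to 141 in the CITCO libraries. Summed over both genes there were 371 counts with DMSO and 386 with CITCO. In a second pair, TRIM74 had 0 counts in the DMSO libraries and 14 to 24 in the CITCO libraries, and its near-identical copy TRIM73 had 68 to 83 and 48 to 86. The sum of this pair was 223 counts with DMSO and 255 with CITCO. How reads shared within either pair were assigned was not tested.

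Several lists not described so far were not called by camera. Heat-shock genes had a median log2 difference within sets of 0.00 over 14 members, and chaperones of the endoplasmic reticulum 0.01 over 24, where XBP1, a transcription factor gene of secretory cells, was higher at 0.21 ± 0.05 when adjusted over the list alone. Targets of p53 had a median of -0.03 over 21 members, with DDB2, a DNA-damage recognition gene, lower at -0.31 ± 0.06 by the same adjustment. Sterol synthesis genes had a median of -0.03 over 24 members and cytotoxic genes 0.02 over 13, with the granzyme gene GZMM lower at -0.32 ± 0.08 over the list alone. The camera adjusted p within sets was 0.992, 0.376, 0.657, 0.376 and 0.934 in this order. Single members differed in other lists when adjusted over the list alone: of 21 genes of IL10 and co-inhibition 4 were higher and 2 lower, including PRDM1, a transcriptional repressor gene (0.16 ± 0.04), of 11 type 2 genes 1 was lower, the cytokine gene IL9 (-0.48 ± 0.10), and of 14 glucocorticoid targets SGK1, a kinase gene, was higher (0.27 ± 0.06) and DDIT4 lower, as over all genes (camera adjusted p = 0.959, 0.672 and 0.446 within sets).

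The matched sets were not a matter of depth. With every library thinned to the smallest total, the lowest correlation of deviations within a set was 0.629. Median between-set variance of 65 T cell receptor V segments was 84.1% of their total, at the 98.8th percentile of 10000 random lists of like expression, against 79% for the median of all genes. Different pools of T cells in the sets, such as separate donors or sorts, are therefore a candidate explanation, and a handling batch shared by the libraries of a set stays open beside it, since the design confounds the 2.

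The rise of CYP2B6 was not explained by reads shared with CYP2B7P, since the summed CPM of both genes still differed 154-fold between the groups. Liver cells would bring albumin far above CYP2B6, and ALB had 4 counts in the CITCO libraries against 5635 of CYP2B6. Activation of CAR or the pregnane X receptor by CITCO may underlie the rise, as the treatment itself stays the open explanation. The values argued against a shared rise of like size among the other 17 measured members of the target list. Their median was -0.0211, with quartiles of -0.0838 and 0.161 and a largest value of 0.604, against 7.94 for CYP2B6. A small shared change cannot be told apart from none, with 7 members positive and 10 negative. Both receptor genes were near the floor, NR1I3 with 21 counts in the CITCO and 32 in the DMSO libraries and NR1I2, which encodes the pregnane X receptor, with 23 and 17, so the counts leave open which receptor acted.

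IL17F, IL22 and IL24, picked because they fell within sets, had a median of -1.03, while IL17A, fixed in advance, was at -0.36 and did not pass (adjusted p = 0.286). A loss of type 17 cells would lower other genes of these cells as well. CCR6, IL23R, KLRB1, IL1R1, PTPN13 and CTSH had a median of 0.0271, and 6 of 6 had a 95% interval wholly above the median of the 3 cytokines. Weaker activation of all cells to the degree of the 3 cytokines was also argued against, since the lower quartile of the activation list was -0.0721. A smaller drop in activation cannot be excluded by this value. Of the 32 members of the list, 6 were lower and 3 higher when adjusted over the list alone. Lower AHR signalling may contribute, as IL22 is known to depend on this receptor, but it cannot be told apart: the AHR list without AHR had a median of -0.185 with 4 of 8 members negative (camera adjusted p = 0.00632 within sets, 0.63 with an estimated correlation, and with AHR in the list 0.0687 and 0.772). The negative members were each lower in 3 of 3 sets, and the others differed from 0 by less than their SE. A direct effect of the treatment on these cytokine genes stays open and untested.

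Splits of the libraries were too few for a share under 0.05. The real grouping gave 1 gene without an added factor, and the highest of the other 9 gave 0. With the set as an added factor the real grouping gave 15 genes and the highest of the other 3 that part every set gave 0, so that 1 of 4 splits, the real one, reached this count. For gene lists, the real grouping gave 11 and the highest other 12 without an added factor, with 4 of 10 splits giving 11 or more. Within sets the real grouping gave 19 lists and the highest other 14.

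These values leave hypotheses to test. If CITCO acts through CAR, which the median of -0.0211 of the other targets leaves open, loss of NR1I3 in these cells would abolish the rise of CYP2B6, and loss of NR1I2 would not. If lower AHR signalling may lower IL22, as the median of -0.185 leaves open, an AHR agonist added with CITCO would restore it. Intracellular staining of IL-17F and IL-22 beside CCR6 would show whether fewer cells make these cytokines or each makes less.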
